A study of Caenorhabditis elegans with 2 samples.

How the data were processed

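ChIP-seq against eGFP-tagged CEH-82 was done in whole L1 larvae of mixed sex, in 2 biological replicates per the labels, which formed 1 group. Peak lists on the assemblies ce11 and ce10 were used. On each assembly the authors deposited 1 list per replicate, 1 list called on both replicates pooled and 1 optimal IDR-thresholded list. Per the deposited read-me files, both replicates were called against the same control alignment, and the optimal list was derived from the pooled list and the lists of both replicates. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The list of replicate 2 holds 30000 peaks on both assemblies, which looks like an upper limit on the number kept, so the lengths of the full lists were not compared as a measure of binding.

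Each deposited list is in narrowPeak format and gives, as the authors' caller wrote them, a signal value per peak, a q-value as −log10, and the position of the summit. The −log10 q-value of the deposited optimal list has a ceiling of 3.82, reached by 83.6% of its peaks, so peaks were ranked by signal, then by q-value. The authors label the pooled list as peaks and background used as input for IDR. Its −log10 q-values go down to 0.0178, and 19.3% of its peaks reach the ceiling. The p-value column of the deposited lists holds no p-values and served only as a further sort key after signal and q-value. Signal values depend on depth and were used only to rank or describe peaks within a list. Peaks are nearly all of 1 width (260 bp for 92.1% of optimal peaks), so widths were not compared between lists. Depth per sample is unknown, since the files give no read counts, and no interval that needs depth is given.

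Coordinates are 1-based on ce11, which is the assembly WBcel235, and all peaks lay within its chromosome lengths. Genes came from the Ensembl annotation and sequence from the RefSeq genome of that assembly. No ce10 genome was used here, so ce10 lists served only for counts, overlaps, chromosome shares and correlations. Each replicate's top list was its 3913 strongest peaks, as many as the optimal list holds. Peaks overlapped when they shared at least 1 bp. Random placements (1000) moved each peak of replicate 1 within its chromosome.

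A peak was represented by its summit. Summits were assigned, in this order, to promoter (1000 bp upstream to 200 bp downstream of the 5' end of any annotated transcript), 5' UTR, coding exon, 3' UTR, non-coding exon, intron or intergenic sequence. Class shares were tested against shares of bases by exact binomial tests and against weaker pooled peaks by Fisher's exact test. The exact binomial p for promoters was too small to be represented as a number and is not printed. A protein-coding gene was bound when a summit lay in the promoter window of any of its transcripts. Genes with more annotated 5' ends thus have more windows, which was not adjusted for. The 31 gene lists were compared with all other protein-coding genes on the 6 nuclear chromosomes by Fisher's exact test. The lists were made from gene names and name patterns, not from expression data. Of the bound genes, 51.1% had a strongest peak that also lay in another gene's window, so a peak between divergent genes counts for both. Short sequences were counted on both strands within 100 bp of the summit and in flanks of the same total length 300 to 400 bp away, with the exact McNemar test over peaks and intervals from 1000 bootstrap draws of peaks. Tests were two-sided, with Benjamini-Hochberg adjustment within lists, sequences, classes or chromosomes and a threshold of 0.05. Genes and peaks are not independent replicates, so these p-values describe this set of peaks, and the spread between replicates is given as mean ± SD of the 2 top lists. Both replicates were called against 1 control, so they can share its errors.

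Genes were named by a rule: the 25 strongest peaks with a promoter window that both replicates' top lists held, up to 4 members of each list with the highest signal, ceh-82 and unc-119, the strongest peak of each chromosome, and the 5 strongest peaks of each replicate outside the optimal list. A peak that this rule names in the chemoreceptor list is not reported here. Groups, tests, gene lists, sequences and most alternatives were fixed before the data were examined. The alternatives were the ce10 lists, the 1956 strongest optimal peaks, reciprocal overlap of 50%, other list lengths, promoter windows of 500 and 2000 bp, each replicate alone, peak midpoints, the nearest gene start, a logistic model with upstream intergenic length and a divergent neighbour, stratification by chromosome, a motif window of 50 bp, promoters of unbound genes, the share of gene starts on X, and windows of 10 and 40 kb around ceh-82 and unc-119. Promoters of protein-coding genes alone and dinucleotide-shuffled windows (5 shuffles of each) were added after the data were seen. So were the comparison of non-coding gene classes and the test of GCGCAGGG.

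The overlap search was checked against bedtools and gave the same counts (3907 and 3754 optimal peaks for replicate 1, at 1 bp and at reciprocal overlap of 50%). The list test was tested on simulated data for 19973 genes with 5 lists at an odds ratio of 5: 99% of changed lists and 0.826% of unchanged lists were called in 100 simulations. In 1000 simulated peaks of which 20% had planted GAGAGA, the ratio was 3.46, and unplanted TAATTA gave 0.941. The simulated genes were bound independently, and simulated summits had the base composition of their flanks. The data differ in both, with peaks shared between genes and GC-rich summits, so these rates need not hold there. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and bedtools 2.31.1.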

Results

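Binding of CEH-82, a homeobox protein of the nematode Caenorhabditis elegans, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole L1 larvae, the first larval stage. The strain carried ceh-82 tagged with enhanced green fluorescent protein (eGFP) on a transgene named as an extrachromosomal array, in an unc-119(ed3) background. The samples formed 1 group of 2 biological replicates, and no peak list of a control immunoprecipitation was analysed here, so the comparisons are between lists, genome features and gene groups rather than between conditions. The authors' lists on ce11 held 24014 peaks in replicate 1, 30000 peaks in replicate 2, 16974 peaks in the list called on pooled replicates and 3913 peaks in the optimal list, which was thresholded by the irreproducible discovery rate (IDR). The 3913 optimal peaks were the 3913 peaks of highest signal in the pooled list, had a median width of 260 bp and covered 0.973% of the genome. Read depth per sample is unknown, because the lists hold no read counts.

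The strongest peaks of the replicates' own lists largely overlapped. Of the 3913 optimal peaks, 3145 (80.4%, exact 95% interval 79.1 to 81.6%) overlapped a peak among the 3913 strongest of replicate 1 and also one among the 3913 strongest of replicate 2. The optimal list was itself selected from both replicates, so this share is in large part fixed by its making. Between the replicates themselves, 3162 of the 3913 strongest peaks of replicate 1 (80.8%) overlapped one of replicate 2, against a mean of 2.06% after 1000 random placements (highest 2.89%). When as many peaks were drawn at random from the full list of replicate 2, the mean overlap was 508.8 peaks (highest 14.7% in 1000 draws). Signal values of the 3162 shared peaks had a Spearman rho of 0.797 between replicates, a description across peaks, which are not independent replicates. With the full lists the overlap of replicate 1 with replicate 2 was 46.7%. The full lists reach down to −log10 q-values of 0.0178 in replicate 1 and 0.0333 in replicate 2, so they include peaks of little support. Intervals on shares of peaks here and below cover counting error only.

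**Figure D1:**
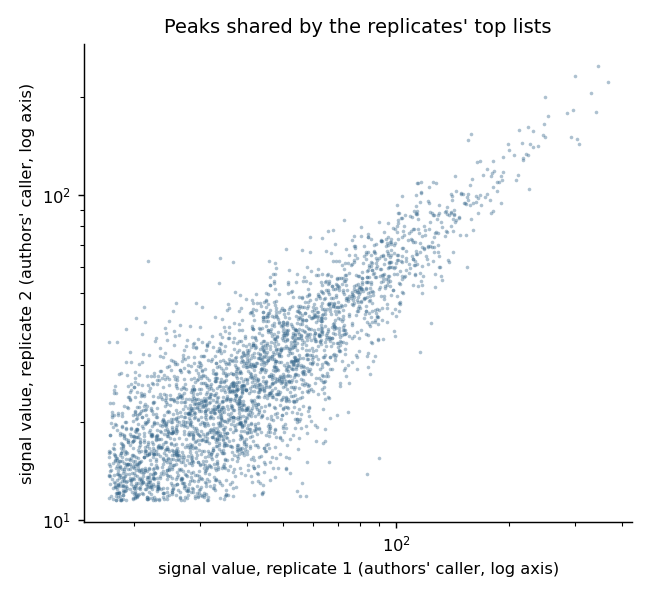
Signal value of each peak shared by the 3913 strongest peaks of replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), as the authors' caller gave it. The 3162 points rise together, with a Spearman rho of 0.797, and scatter most at low signal.

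Ribosomal protein genes stood out among the strongest promoter peaks. Among the 25 strongest peaks that had a protein-coding gene's promoter window (1000 bp upstream to 200 bp downstream of a transcript's 5' end) and were present in both replicates' top lists, 9 lay at ribosomal protein genes, 11 were on chromosome III, and 14 lay in the windows of more than 1 gene. The first, with a signal of 595.3, was on chromosome III at 10759135 to 10759377, 58 bp upstream of tasp-1 and 727 bp upstream of K01G5.10, outside protein-coding gene bodies. The next were 274 bp upstream of rpl-3 (signal 586, chromosome III, 3867469 to 3867679), 353 bp upstream of rpl-15 and 461 bp upstream of K11H12.8 (534, chromosome IV, 654823 to 655033) and 172 bp upstream of cdc-48.1, which encodes the AAA ATPase that extracts ubiquitinated proteins (531, chromosome II, 10563480 to 10563675). In replicate 1 these 4 peaks had signals of 345, 366, 330.3 and 300.1, and in replicate 2 signals of 249, 222, 206 and 231, on each list's own scale.

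Further down the same ranking stood rpl-35 (signal 475), eelo-2 (461), nspc-17 on X (451), rpl-20 with Y17G9B.5 (450.3), rps-20 with ekl-4 (401), and egl-30 with C53H9.4 (391), where egl-30 encodes the Gq alpha subunit. They were followed by rpl-12 with lin-54 (386), rps-12 with ska-3 (383), rps-28 with Y41D4B.4 (367), ins-39 on X (360.0), iff-2 with F54C9.14 (359), and rps-1 with ifet-1 (356). Also among the 25 were Y39E4B.6 (351), sec-61.G with F32D8.13 (345), K12H4.5 (342), cox-5A (339), cox-6B with nduc-2 and Y71H2AM.20 (324), larp-1 with wip-1 (316), the histone gene his-37 (313), hsp-110 with rpn-3 (313), and ints-4 (305). The strongest peak of chromosome I was the one at rps-20 and ekl-4, and that of chromosome V the one at sec-61.G and F32D8.13 (chromosome V, 10897278 to 10897451). On X it was intergenic, at 11094040 to 11094371, with a signal of 512.

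Binding was concentrated in promoters and nearly absent from coding exons outside promoter windows. Of the 3913 optimal summits, 3054 (78.0%, exact 95% interval 76.7 to 79.3%) fell in the promoter window of an annotated gene of any kind, and the replicates' own top lists gave 77.3% ± 0.560 (SD, n = 2). Promoter windows held 38.6% of the bases of the genome, so the share was 2.02 times that of bases. With windows of protein-coding genes alone, added after the data were seen, 63.4% of summits lay in promoters, against 26.2% of bases. Coding exons outside promoter windows held 11 summits (0.281%) against 16.99% of bases, introns 305 (7.79%) against 24.2% and intergenic sequence 514 (13.1%) against 16.3%. The 13061 weaker pooled peaks, which did not enter the optimal list, had 47.9% of summits in promoters and 8.61% in coding exons outside promoter windows (odds ratio for promoters 3.87, Fisher's exact test, two-sided, adjusted p = 3.34e-255). The authors label the pooled list as peaks and background, so this contrast is in part one with background rather than with weaker binding sites. Within the optimal list the promoter share was 86.1% among the 978 strongest peaks and 69.2% among the 979 weakest.

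Summits sat mostly upstream of the nearest protein-coding 5' end, with a median position of -204 bp, 80.1% upstream and 33.2% within 200 bp. For the weaker pooled peaks these shares were 56.7% and 14.4%. Annotated 5' ends in this species are often trans-splice sites rather than transcription starts, which limits how exactly such distances place a summit.

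**Figure D2:**
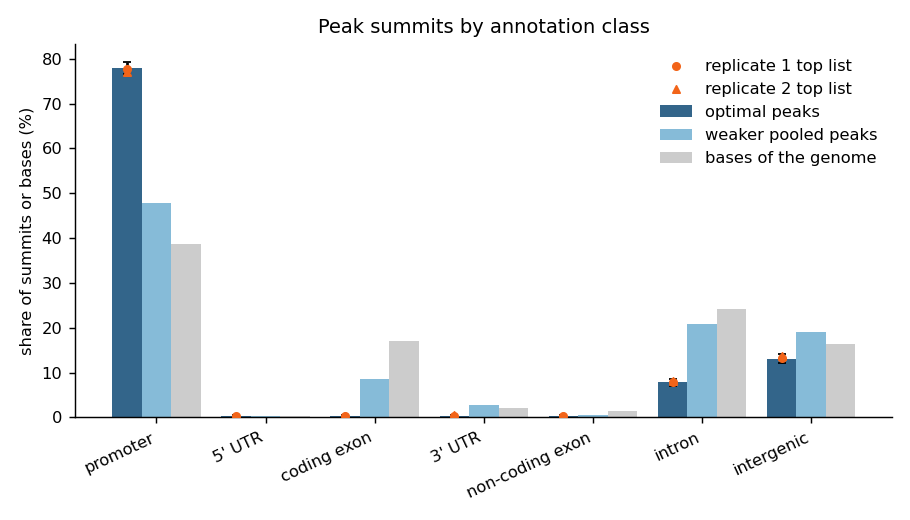
Share of peak summits or bases (y axis, %) in each annotation class (x axis) for the optimal list (dark bars, with exact 95% intervals), the weaker pooled peaks and the bases of the genome, with each replicate's top list as points. Promoters hold 78.0% of optimal summits, 47.9% of weaker summits and 38.6% of bases.

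Genes of the translation machinery, the proteasome and the mitochondrion were bound far more often than other genes. An optimal summit lay in the window of 3201 of 19973 protein-coding genes (16.03%), and the replicates' top lists gave 3157 ± 43.8 genes (SD, n = 2), of which 2742 were in both. Of 83 genes for cytosolic ribosomal proteins 75 were bound (90.4%, odds ratio 50.3, 95% interval 24.2 to 121), and each replicate's top list gave the same percentage. Of 33 proteasome genes 27 were bound (81.8%, replicates 80.3% ± 6.43, SD, n = 2, odds ratio 23.8), among them rpn-3 (signal 313), rpn-9 (127), rpn-11 (126.2) and rpt-2 (118.8). Of 33 translation factor genes 25 were bound (75.8%, odds ratio 16.5), with iff-2 (359), ifet-1 (356), eef-1A.1 (248) and eef-2 (247) the highest. Of 64 respiratory chain genes 42 were bound (65.6%, replicates 64.8% ± 3.31, SD, n = 2, odds ratio 10.1), led by cox-5A, nduc-2, cox-6B and cox-5B (297). Of 70 mitochondrial ribosomal protein genes 35 were bound (replicates 47.9% ± 5.05, SD, n = 2, odds ratio 5.29), led by mrps-7 (252), mrpl-28 (215), mrpl-49 (165) and mrpl-55 (159).

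Other groups with a raised share were splicing factors, with 29 of 47 bound (61.7%, odds ratio 8.51), including snr-4 (signal 225), prp-19 (206), prp-8 (202) and rsp-1 (183). Cell cycle and replication genes had 34 of 60 bound (56.7%, replicates 57.5% ± 3.54, SD, n = 2, odds ratio 6.91), with cdc-48.1, cdk-7 (205), efl-1 (196) and knl-3 (192) at the top. Heat shock proteins and chaperonins had 32 of 60 bound (53.3%, odds ratio 6.04), including hsp-110 (313), cct-8 (302), cct-1 (263) and hsp-90 (226). Across these lists Fisher's exact test (two-sided, Benjamini-Hochberg over 31 lists) gave adjusted p-values from 1.76e-49 for ribosomal proteins to 1.14e-10 for mitochondrial ribosomal proteins. When each summit went to its nearest gene start alone, so that a shared peak counted for 1 gene, the odds ratios were 7.38 for ribosomal proteins, 8.57 for the proteasome and for translation factors, 5.23 for the respiratory chain, 4.85 for splicing factors, 3.06 for mitochondrial ribosomal proteins and 2.82 for heat shock proteins. In the 1956 strongest peaks that of the proteasome was 10.3.

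Genes that all neurons use and genes that time larval development were also bound often, and neuropeptide and insulin genes rarely. The number of annotated transcripts per gene, each with its own window, was not adjusted for in these comparisons. Of 34 pan-neuronal genes 20 were bound (58.8%, replicates 57.4% ± 2.08, SD, n = 2, odds ratio 7.53, Fisher's exact adjusted p = 4.29e-08). The highest were the synaptobrevin gene snb-1 (signal 289), rab-3 (121), unc-11 (116) and sbt-1 (114). Of 16 heterochronic genes, which set the timing of larval cell fates, 10 were bound (62.5%, replicates 59.4% ± 13.3, SD, n = 2, odds ratio 8.76, Fisher's exact adjusted p = 6.71e-05), with nhl-2 (273), lin-66 (133), lin-28 (101) and the Argonaute gene alg-2 (80.5) the strongest. Only 3 of 143 neuropeptide and insulin genes were bound (2.098%, odds ratio 0.111, Fisher's exact adjusted p = 2.69e-07), namely ins-39 (360.0), flp-23 (45.5) and nlp-4 (43.4, the same peak as exos-3), and none of 19 neurotransmitter genes (adjusted p = 0.0833). Of 29 Wnt pathway genes 10 were bound (34.5%, replicates 31.0% ± 4.88, SD, n = 2, odds ratio 2.76, Fisher's exact adjusted p = 0.0294), including mig-5 (263, the same peak as cct-1), lit-1 (78.1), wrm-1 (65.2) and pop-1 (58.1). The Wnt result was lost in the top list of replicate 2 alone (odds ratio 2.06, exact adjusted p = 0.159), with windows of 500 bp (2.11) and in the 1956 strongest peaks (1.54). The heterochronic odds ratio was 5.40 in the top list of replicate 2 alone, 5.79 in the 1956 strongest peaks, 5.16 with 500 bp and 27.6 with 2000 bp, where the pan-neuronal one was 12.8 and that of neuropeptides and insulins 0.171 (0.0673 in the 1956 strongest).

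Genes of chemoreceptors, nuclear hormone receptors, lectins, F-box proteins, collagens, intestine and hypodermis were bound less often than other genes. Of 1365 chemoreceptor genes 17 were bound (1.25%, replicates 1.21% ± 0.155, SD, n = 2, odds ratio 0.0611, 95% interval 0.0354 to 0.0984, Fisher's exact adjusted p = 1.64e-79). For 10 of these 17 the strongest peak also lay in the window of a gene outside the family, such as rsr-1 beside sri-5 (signal 212) and clic-1 beside srr-10 (113). Intestinal genes had 2 of 107 bound (1.87%, odds ratio 0.0992), namely cpr-9 (54.5) and erm-1 (33.1), and hypodermal and seam genes 3 of 77 (3.90%, odds ratio 0.212), namely ajm-1 (73.1), grl-26 (39.6) and tps-1 (33.4). Of 178 cuticle collagen genes 7 were bound (3.93%, odds ratio 0.213), including col-38 (195, the same peak as rpl-5), col-2 (98.7), bli-6 (93.6) and col-71 (89.9). Another gene's window also held the strongest peak of 5 of these 7. C-type lectins had 5 of 240 bound (2.08%, odds ratio 0.110), led by clec-140 (94.9), clec-104 (93.1), clec-53 (70.4) and clec-87 (50.8). The strongest peak of 4 of these 5 also lay in another gene's window. F-box and BTB/MATH protein genes had 21 of 412 bound (5.10%, odds ratio 0.277), led by bath-42 (202, shared with prp-8), fbxb-85 (198), fbxa-90 (196, the same peak as efl-1) and math-33 (78.9). Such sharing held for 12 of these 21. Nuclear hormone receptor genes had 29 of 274 bound (10.6%, replicates 10.04% ± 0.774, SD, n = 2, odds ratio 0.617, Fisher's exact adjusted p = 0.0217), led by nhr-47 (183), nhr-142 (138), nhr-49 (117) and nhr-255 (106). When each summit went to its nearest gene start, the hypodermal result (odds ratio 0.388, Fisher's exact adjusted p = 0.0961) and the nuclear hormone receptor result (0.871) were lost, the latter also with upstream length as covariate (0.679) and by chromosome (0.793), and the odds ratio of lectins was 0.0589. The intestinal odds ratio ranged from 0.0505 to 0.151 with 1 replicate left out and from 0.0622 to 0.152 with 500 and 2000 bp (0 in the 1956 strongest peaks), and the hypodermal one from 0.0868 to 0.331 with 500 and 2000 bp (0.126 in the 1956 strongest, where nuclear hormone receptors had 0.399).

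**Figure D3:**
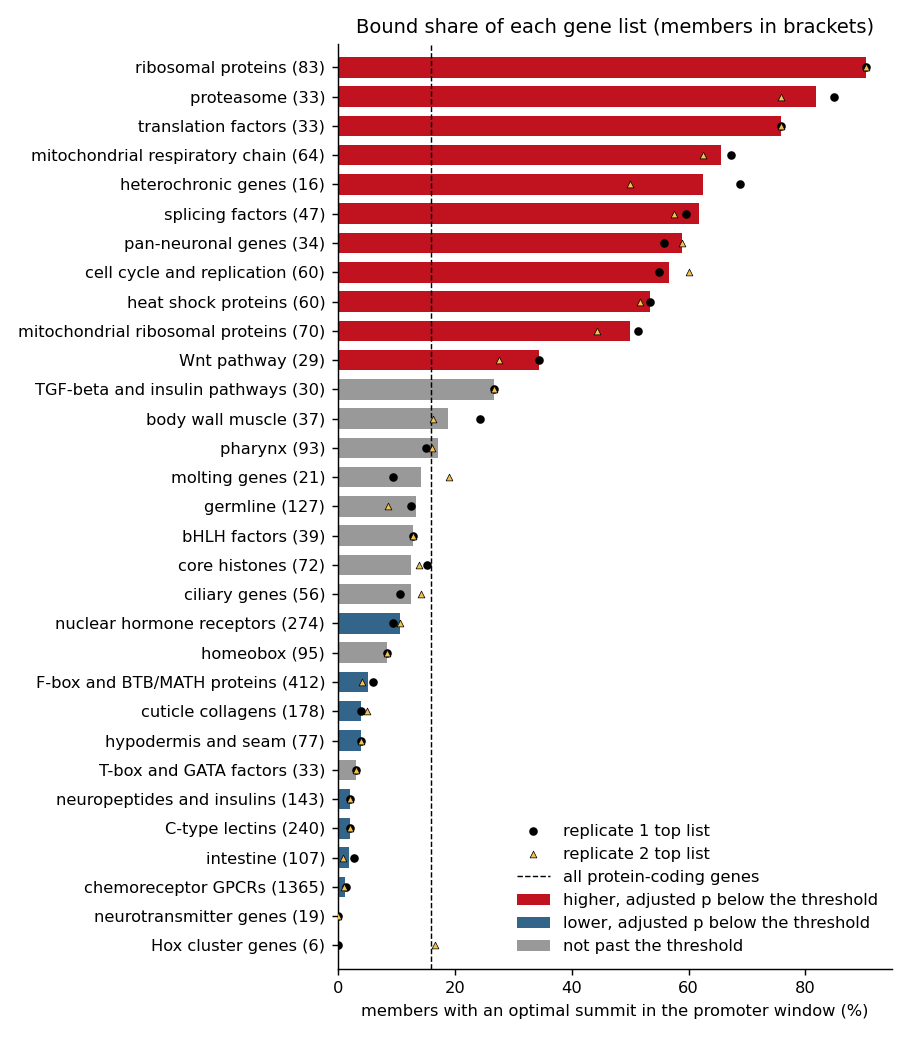
Percentage of the members of each of 31 gene lists with an optimal summit in the promoter window (bars, x axis), with each replicate's top list as points and the share of all protein-coding genes as a dashed line at 16.03%. Ribosomal proteins are highest at 90.4%, and chemoreceptors, neurotransmitter genes and Hox cluster genes are at or below 1.25% in the optimal list.

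The remaining 12 of the 31 lists did not pass the threshold, among them the family of ceh-82 itself. Of 95 homeobox genes 8 were bound (8.42%, odds ratio 0.481, Fisher's exact adjusted p = 0.0748), with ceh-38 (signal 169), ceh-39 (81.2), unc-62 (54.2) and ceh-20 (41.6) the highest, and none of 6 Hox cluster genes was bound (adjusted p = 0.687). T-box and GATA factors had 1 of 33 bound (3.03%, Fisher's exact adjusted p = 0.0774), egl-27 (31.5), and bHLH factors 5 of 39 (12.8%, adjusted p = 0.854), with mdl-1 (162), hif-1 (111), hlh-30 (97.9) and aha-1 (85.996) on top. Members of the TGF-beta and insulin pathways had 8 of 30 bound (26.7%, Fisher's exact adjusted p = 0.176), including akt-2 (89.6), daf-16 (75.3), daf-3 (61.0) and sma-9 (60.4). Also among these lists were body wall muscle (7 of 37, Fisher's exact adjusted p = 0.722), pharynx (16 of 93, adjusted p = 0.830), histone genes (9 of 72, adjusted p = 0.645), ciliary genes (7 of 56, adjusted p = 0.687), germline genes (17 of 127, adjusted p = 0.605) and molting genes (3 of 21, adjusted p = 1). Their strongest members were unc-60 (94.9), pqn-70 (241), his-37 (313), ift-43 (135), puf-9 (295) and myrf-1 (143). The pharynx list takes in every gene named pqn, and the germline list every gene named puf or rme, whatever their site of expression. The shares of these lists therefore need not describe those tissues. Homeobox genes passed the threshold in the 1956 strongest peaks (odds ratio 0.206, Fisher's exact adjusted p = 0.0136) and by chromosome (0.463, against 0.481), and germline genes in the top list of replicate 2 alone (0.509, Fisher's exact adjusted p = 0.0443, against 0.809). T-box and GATA factors passed with windows of 500 bp (odds ratio 0, against 0.163) and 2000 bp (0.123) and by chromosome (0.149), and TGF-beta and insulin pathways with 2000 bp (3.45, against 1.91).

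Summits were rich in GA repeats and in CG-containing sequence, and poor in the TAATTA core that many homeodomain proteins bind. GAGAGA occurred within 100 bp of 47.6% of optimal summits and in 11.8% of the flanks 300 to 400 bp away (ratio 4.03, bootstrap 95% interval 3.69 to 4.42, replicates 3.91 ± 0.0741, SD, n = 2). TAATTA occurred at 4.04% of summits and in 11.2% of flanks (ratio 0.360, interval 0.300 to 0.425, replicates 0.393 ± 0.00538, SD, n = 2). By the exact McNemar test (two-sided, Benjamini-Hochberg over 10 sequences) the adjusted p was 4.05e-254 for GAGAGA and 5.26e-33 for TAATTA. TAAT (59.9% against 88.3%), TTAATTAA (0.767% against 2.22%), TGATAA (6.80% against 18.2%) and ATATAT (5.37% against 9.99%) were also rarer at summits. The E-box sequences CACGTG (5.42% against 3.32%) and CAGCTG (5.75% against 3.63%) were more common there, as was TTGCGCAA (0.869% against 0.409%), and TGACTCA did not differ past the threshold (2.096% against 2.22%, exact adjusted p = 0.750). Within 50 bp of summits the ratio was 0.163 for TAATTA, 0.111 for TTAATTAA, 0.212 for TGATAA and 0.273 for ATATAT. Against promoters of unbound genes TTAATTAA no longer passed (ratio 0.703).

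Among all 2080 6-mers, counted on both strands, GCGCGC had the highest ratio of summit to flank (6.69), followed by CGCGCG (6.23) and ACGCGC (6.17), with GAGAGA at rank 28. GCGCGC was at 11.9% of summits. Some 6-mers with somewhat lower ratios lay at more summits, namely ACGCAG (26.4%, flanks 4.27%, ratio 6.15) and GACGCA (24.97%, flanks 4.27%, ratio 5.82). The same held for GAGACG (30.5%, flanks 5.98%, ratio 5.08) and AGACGC (24.6%, flanks 4.83%, ratio 5.08). These sequences overlap, and whether they mark a longer sequence was not tested. TAATTA was 20th from the lowest. Median GC content was 44.5% in the 200 bp around optimal summits, 38.0% around weaker pooled summits and 35.4% in the genome. Against dinucleotide-shuffled copies of the same summit windows, a comparison chosen after the data were seen, the TAATTA ratio was 0.874 (exact McNemar test against 1 shuffled copy, adjusted p = 0.402), TTAATTAA had 0.898, ATATAT turned to a ratio of 3.10 and TTGCGCAA to 0.934, while GAGAGA kept a ratio of 2.23, TAAT one of 0.887 (exact McNemar test, adjusted p = 1.12e-12) and TGATAA one of 0.7097.

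**Figure D4:**
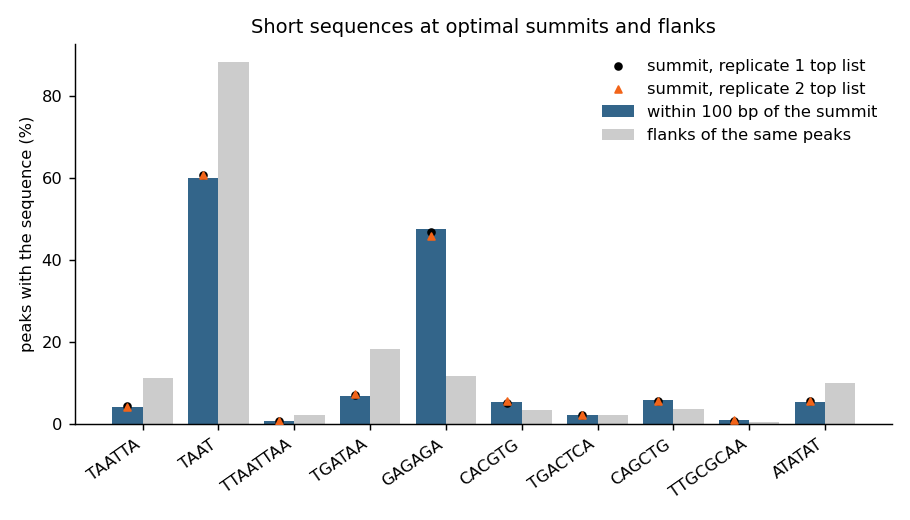
Percentage of optimal peaks (y axis) with each of 10 short sequences (x axis) within 100 bp of the summit and in the flanks of the same peaks, with each replicate's top list as points for the summit. GAGAGA is at 47.6% of summits and 11.8% of flanks, and TAATTA at 4.04% and 11.2%.

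Chromosomes I and III carried more peaks than their length gave and chromosome V fewer. Chromosome I held 19.04% of optimal peaks and 15.03% of bases (replicates 19.1% ± 0.0542, SD, n = 2), and chromosome III 18.4% of peaks and 13.7% of bases (replicates 18.1% ± 0.0723, SD, n = 2), with exact binomial adjusted p-values of 2.28e-11 and 1.67e-15. Chromosome V held 14.2% of peaks and 20.9% of bases (replicates 14.1% ± 0.343, SD, n = 2, exact binomial adjusted p = 9.74e-26) and chromosome IV 15.8% against 17.4% (exact adjusted p = 0.0105), while chromosome II held 14.6% against 15.2% (exact adjusted p = 0.368). The share on X, 17.9% (exact 95% interval 16.7 to 19.1%, replicates 18.2% ± 0.199, SD, n = 2), did not differ past the threshold from its 17.7% of bases (exact adjusted p = 0.753), and exceeded its 13.7% of protein-coding gene starts (exact binomial p = 2.08e-13). Against gene starts, chromosome IV no longer differed (16.4%, exact binomial p = 0.311) and chromosome II was lower (14.6% of peaks against 17.3% of gene starts, exact binomial p = 9.79e-06).

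X peaks were frequent among the 25 and 50 strongest peaks but not among the 100 strongest, a feature singled out after the data were seen. Of the 25 strongest peaks 10 were on X (9 and 10 in the replicates' own top 25), and of the 50 strongest 16 were (17 and 14 in the replicates). Of the 100 strongest 19 were (18 and 24 in the replicates), which did not differ past the threshold from the 17.7% of bases on X (exact binomial p = 0.695) or from the share among the other optimal peaks (odds ratio 1.08, Fisher's exact test, two-sided, p = 0.791). Of these 19 peaks, 11 lay outside promoter windows, among them the strongest, at 11094040 to 11094371, another intergenic one at 806584 to 806803 (signal 452) and one in an intron of mom-1 at 6296407 to 6296721 (signal 399.7). The 81 autosomal peaks among the 100 strongest had 95.1% of summits in promoter windows, against 42.1% of the 19 on X. The sequence GCGCAGGG lay within 100 bp of the summit in 10 of the 19 X peaks (52.6%, exact 95% interval 28.9 to 75.6%) and in none of the 81 autosomal ones (Fisher's exact test, two-sided, p = 5.34e-09), with 10 X peaks holding it in each replicate's own 100 strongest as well. The optimal peaks upstream of nspc-17 and ins-39 were among those that held it.

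**Figure D5:**
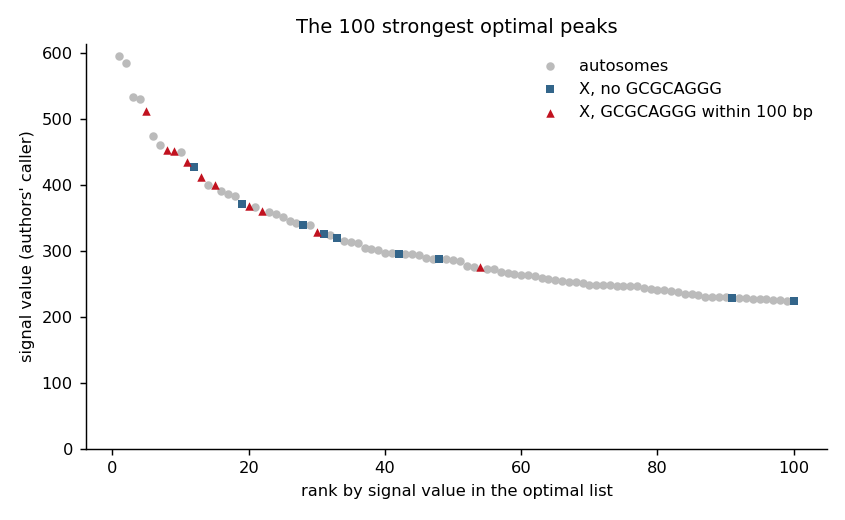
Signal value (y axis) of the 100 strongest optimal peaks by rank (x axis), with autosomal peaks in grey, X peaks without GCGCAGGG near the summit as squares and X peaks with it as triangles. X holds 10 of the first 25 peaks, and 10 of its 19 peaks among the 100 have the sequence.

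The ceh-82 gene itself had no optimal peak nearby, and unc-119, named in the strain's genotype, had several. Within 20 kb of ceh-82 (chromosome II, 1732232 to 1733291) there were 0 optimal peaks and 3 weaker pooled peaks, the strongest with a signal of 19.1 at rank 5558, and 27.3% of 10000 random protein-coding genes had no optimal peak either. Within 20 kb of unc-119 (chromosome III, 10902641 to 10908935) there were 4 optimal peaks, more than around 85.99% of the random genes. Of these, 3 had summits inside the gene, the strongest in an intron at 10905210 to 10905469 with a signal of 180.1 at rank 197, and signals of 113 and 65.5 in replicates 1 and 2. Within 40 kb of unc-119 there were 7. A source label also speaks of an insertion, although the transgene's name is that of an array. Its content is not known here, including whether it carries unc-119. Signal from any copies of either gene therefore cannot be separated from that of the endogenous loci.

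The strongest peaks of a replicate's own list that were missing from the optimal list ranked well below its top. The 5 strongest of replicate 1 were upstream of kin-14 (signal 27.01 in replicate 1, rank 2510), in the body of mbl-1 (26.8), intergenic on X at 6248857 to 6249112 (25.9) and on chromosome II at 6891322 to 6891577 (25.7), and inside egl-30 (24.5). The last was also in replicate 2 (signal 18.4, rank 2430) and had no pooled peak. The 5 strongest of replicate 2 were in an intron of nhr-14 (signal 23.7 in replicate 2, rank 1783), at haf-7 (21.6), at cyp-13A2 (20.7), upstream of both nol-14 and xpo-2 (20.1) and intergenic on chromosome V at 13396404 to 13396663 (19.8).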

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

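The comparison with dinucleotide-shuffled windows and that with protein-coding promoters alone were chosen after the data were seen. Of 358 values under other settings, 315 kept their direction and side of the threshold, stayed within their spread or, for counts, within 1.5 times the reported one (bound genes ranged from 2466 with the nearest gene start to 4053 with 2000 bp). The strongest results, those for ribosomal proteins, proteasome, translation factors, respiratory chain, splicing, cell cycle, heat shock, mitochondrial ribosomal, pan-neuronal and heterochronic genes, chemoreceptors, lectins, collagens, F-box proteins, neuropeptides and intestine, kept direction and call under all 8 settings tried, as was the promoter share under all 7. With 50% of the peaks, those of higher signal, the optimal list held 1956 peaks, 99.6% of them in both replicates' top lists, and 1879 genes were bound. Reciprocal overlap of 50% gave 74.4% for optimal peaks in both top lists and 77.4% between replicates, and the full lists gave 99.6% and 46.7%. Within 40 kb of unc-119 there were 7 peaks. The share on X fell to 17.2% in the 1956 strongest, below the share of bases, and its excess passed the threshold when gene starts gave the expected share (17.9%).

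Odds ratios that lost their call were those of nuclear hormone receptors (0.871 with the nearest gene start, 0.679 with upstream length as covariate, 0.793 by chromosome), hypodermis (0.388 with the nearest gene start) and Wnt genes (1.54 in the 1956 strongest, 2.11 with 500 bp). Those that gained one were homeobox (0.206 in the 1956 strongest, 0.463 by chromosome), T-box and GATA factors (0 with 500 bp, 0.123 with 2000 bp, 0.149 by chromosome) and TGF-beta and insulin pathways (3.45 with 2000 bp) and germline genes (0.509 without replicate 1). Wnt genes lost theirs without replicate 1. Without replicate 1 or 2, odds ratios ranged from 2.06 to 2.78 for Wnt, 0.0505 to 0.151 for intestine, 0.509 to 0.758 for germline, 0 to 1.08 for Hox, 0.933 to 1.04 for pharynx and 0.554 to 1.27 for molting genes, and the TGACTCA ratio from 0.921 to 1.02. Uncalled lists changed direction for bHLH factors (1.42), histone genes (1.04) and molting genes (1.01) in the 1956 strongest, pharynx (0.709 with 500 bp, 0.815 with 2000 bp), and molting genes (1.18 with the nearest gene start, 1.01 with covariates). The TGACTCA ratio was 1.09 with 50 bp and 1.20 against unbound promoters. Against unbound promoters TTAATTAA (0.703) lost its call. Against shuffled windows TAATTA (0.874) and TTAATTAA (0.898) lost theirs, TGACTCA (0.787) gained one, and TTGCGCAA (0.934) and ATATAT (3.10) reversed. The cause of the other changes was not tested. Models with covariates could not be fitted for the 2 lists with no bound member. No setting adjusted for the number of annotated transcripts per gene. Unknown depth limits how far weak peaks of 1 replicate can be compared with the other.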

Other observations

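The test of signal on X in general, reworded after its values had been seen, and that of TAATTA in the promoters of 3 gene lists, the comparison with shuffled windows and the comparison of non-coding genes were chosen after the related results had been seen. tRNA and snoRNA genes had peaks nearby more often than protein-coding genes. An optimal summit lay within 500 bp of the 5' end of 212 of 612 tRNA genes (34.6%, replicates 33.4% ± 0.809, SD, n = 2) and of 30.1% of 346 snoRNA genes (replicates 29.8% ± 0.409, SD, n = 2), against 12.6% of protein-coding genes (odds ratios 3.69 and 2.99, Fisher's exact adjusted p = 9.30e-43 and 3.62e-17). The shares for snRNA genes (12.4%), miRNA genes (12.6%) and lincRNA genes (10.3%) did not differ past the threshold from that of protein-coding genes (Fisher's exact adjusted p = 1, 1 and 0.539). Pseudogenes (35 of 2128, 1.64%) and piRNA genes (192 of 15363, 1.25%) had few, and neighbouring members of such clusters can share a peak. Signal that any immunoprecipitation may give at open or highly transcribed loci was not tested for these gene classes. No control list was analysed here.

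The strongest X peaks differ from the strongest autosomal peaks in position and sequence. A general excess of signal on X stays open, since X, with 17.7% of bases, held 17.8% of the optimal peaks outside the 100 strongest (exact 95% interval 16.6 to 19.1%) but 21.95% of the weaker pooled peaks (21.2 to 22.7%). The weaker pooled peaks include background by the authors' label, so their share on X need not describe binding sites. A hypothesis is that some of the strongest X peaks are recruitment sites of the dosage compensation complex, which is recruited to X in part through the MEX motif, whose core GCGCAGGG lay at 52.6% of the X peaks among the 100 strongest and at 0 of the 81 autosomal ones. Over the whole genome the sequence is only modestly denser on X (4.57 per Mb, against 2.82 on the autosomes). The other 9 of these 19 X peaks lack the core, and such sites may also be open chromatin that any immunoprecipitation recovers, which was not tested, as no control list was analysed here.

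The binding of ribosomal protein, proteasome and translation factor promoters is not wholly accounted for by short or shared upstream regions. With upstream length and a divergent neighbour as covariates, the smallest of the 3 odds ratios was 16.5 (95% interval 7.26 to 37.3, translation factors), and with each summit given to its nearest gene start alone it was 7.38 (4.67 to 11.7, ribosomal proteins, down from 50.3), so shared windows can account for part of the size. Signal from open or highly transcribed promoters, which any chromatin immunoprecipitation may give, stays open. Over the 125 peaks in these promoters TAATTA was at 5 summits and in 14 flanks (ratio 0.357, interval 0.0909 to 0.90), so the peaks show no homeodomain core that would argue against it, but the sequence CEH-82 itself prefers is not known here and a control immunoprecipitation was not analysed here. GAGAGA was at 21.6% of these 125 summits and in 15.2% of their flanks, against 47.6% and 11.8% for all optimal peaks. No biological explanation was tested, as the design has 1 group.

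The rarity of TAATTA at summits could come from the base composition of the summit windows, which are GC-rich, but that of TAAT is not wholly accounted for by it (0.887 against shuffled windows, interval 0.866 to 0.907). Against dinucleotide-shuffled copies of the same windows the TAATTA ratio was 0.874 with an interval of 0.742 to 1.01, which includes no difference. Position relative to a gene start alone does not account for the rarity of TAATTA. Against the same offsets in promoters of unbound genes the ratio was 0.443 (interval 0.355 to 0.536). Those promoters were not matched for base composition or activity, and the AT-rich ATATAT also fell there (0.557). The comparison therefore cannot exclude that TAATTA is rare in active promoters in general. No biological explanation was tested.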
